A study of Rattus norvegicus with 24 samples.

How the data were processed

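Total RNA from the thyroid glands of adult male Sprague-Dawley rats was hybridised to 24 Affymetrix expression arrays, 1 sample per array. Per the labels, RNA was extracted with Trizol and cleaned on an RNeasy column, and targets were made with biotin by the manufacturer's standard protocol. The 24 samples form 8 groups of 3: at each of 2 times (1 day and 14 days), untreated controls on normal diet and water, rats given perchlorate, rats on an iodine-deficient diet, and rats given both. Housing and feeding lasted 2 months plus the 1 or 14 days. Perchlorate was given in the drinking water at 95 mg of the potassium salt per liter. The group and the sample number of each array were taken from its title, and no array was left without a group. Nothing in the labels says that each sample came from a separate animal, so p-values measure only the spread between these samples, which may be partly technical.

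The deposited values are linear signal intensity per probe set (a set of short probes for 1 transcript), summarised with GCOS, per the submitters' processing notes; the software's version is not given in the sources used here. Neither the summarising algorithm's settings nor the scaling target is given in the sources used here. The trimmed mean intensity (2% trimmed) of the deposited columns ran from 322 to 489, so the arrays had not been brought to 1 common mean. The table held 31099 probe sets, of which 57 are hybridisation and quality controls and were left out of every test. Detection calls and probe-level values were not used here, so the signal over background of a single probe set is unknown, and the number of arrays limits the precision.

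Values were computed as log2(intensity + 16), and a log2 fold change is on that scale, which understates the change of dim probe sets. The rule fixed in advance was quantile normalization between arrays if the array medians spanned over 0.5, and the medians ran from 6.63 to 7.19, a span of 0.56, so quantile normalization was used. Probe sets below the 40th percentile of mean log2 signal over all arrays were left out, which left 18625 of 31042 for testing. Each was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 arrays, so that the groups share 1 estimate of the spread. Contrasts were tested with eBayes and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested in each comparison. A probe set was called at an adjusted p under 0.05. Every adjusted p of a single gene is from this limma model, and SE is the standard error of its log2 fold change. SD is the standard deviation over the 3 arrays of a group.

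There were 14 comparisons fixed before the data were examined. They set the deficient diet (each day and the mean of both days), perchlorate (each day) and both together (each day) against the control of the same day. Perchlorate was also set against no perchlorate on the deficient diet, and the diet against perchlorate directly, on each day. The interaction of diet and perchlorate on each day, and the perchlorate effect at day 14 minus that at day 1, were tested as contrasts of contrasts. A comparison of the diet effect at day 14 with that at day 1 was added after seeing the data.

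Probe sets were named from the platform's annotation: 20826 of the non-control probe sets carried 1 symbol, 436 several and 9780 none, and only those with 1 symbol were named. Symbols were checked by Entrez number against a RefSeq gene table of assembly GRCr8, which held 20758 of the symbols and changed 0 of them. From that table the genomic span of genes was used in 1 check of array quality, and no coordinates are given because the array's annotation names no build. A gene with several probe sets is represented by the one with the highest mean signal, which gave 10643 genes. Statements about a gene refer to that probe set, and the text says where other probe sets of a gene differed in their calls.

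The genes named follow a rule fixed before the data were examined. In each comparison these are the 12 largest rises and 12 largest falls among representative probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of the groups compared (chance gives no overlap for 10% of probe sets with 3 arrays against 3). For the mean of both days the arrays must not overlap within either day. For the interactions and the difference between days it is the 6 largest rises and 6 largest falls, with no condition on overlap. To these are added the measured members of the list of thyroid hormone synthesis and iodide handling, and of each other list up to 4 members with the smallest p. Fewer were printed where the text would only repeat values, and a gene outside the rule is said to have been chosen after its values were seen.

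Gene lists were written before the data were examined: 24 lists with 586 genes, of which 446 were measured. They cover thyroid hormone synthesis and iodide handling; thyroid transcription factors and follicular identity; cell cycle and DNA replication; immediate early and cAMP-responsive genes; endoplasmic reticulum folding and unfolded protein response; angiogenesis signals; antioxidant and hydrogen peroxide defence; mitochondrial oxidative phosphorylation; glycolysis and glucose uptake; lysosome and thyroglobulin processing; cholesterol synthesis; ribosome biogenesis; extracellular matrix and fibroblasts; basement membrane; and thyroid hormone responsive genes. A further set holds markers of C cells and neuroendocrine cells, parathyroid, skeletal muscle, adipocytes, endothelium, lymphocytes and thymus, macrophages and mast cells, cartilage and trachea, and red blood cells. Each list was tested against all other genes with limma's camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Beside it, camera was run with a correlation estimated from the data, and fry tested whether a list's genes moved, on balance, one way, without comparing them with other genes. Per list, the text gives the members called over all probe sets and the number called when adjusted over the list alone.

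The likeness of 2 effects was measured as the Pearson correlation and covariance of log2 fold changes over the 18625 probe sets; probe sets are not independent replicates, so no p-value is given. Effects measured against the same 3 control arrays share their chance values, so 100 pairs of unchanged groups were simulated against shared controls. The alternatives fixed in advance were a pseudocount of 1 or 64, the values as deposited without quantile normalization, no filter on dim probe sets, a fit with only the groups compared, and leaving out each array in turn. For the lists, the mean of all probe sets of a gene, the values as deposited and an estimated correlation were fixed in advance too. Array quality weights, and a fit without the 2 day 1 arrays that stood apart, were added after seeing the data. So was a regrouping of residuals for the interactions and the perchlorate difference between days, in which the additive effects were fitted, their residuals permuted over the 12 arrays 100 times (the real grouping included) and the calls counted again. The numbers of the samples are unique to each group and pair nothing.

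The pipeline was tested on simulated data with the real probe sets' means and spread. For perchlorate against control at day 14, limma recovered 4.48% of probe sets changed by 0.5 on the log2 scale, 50.7% of those changed by 1 and 97% of those changed by 2, with 0 false calls among 18625 probe sets. For the interaction at day 14, with the same number of changed probe sets, the shares were 7.46%, 29.9% and 84.8%, with 3 false calls. With 20 simulated lists of 20 genes drawn at random, camera called the 1 list that had been moved and 0 of the unmoved lists. The lists tested on the real data hold related genes, so this does not show that the preset correlation fits them.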

Results

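Thyroid transcripts were measured in 24 samples from adult male rats in 8 groups of 3: untreated controls, perchlorate, an iodine-deficient diet, and the diet with perchlorate, each at day 1 and day 14. Perchlorate is an anion that blocks the uptake of iodide into thyroid follicular cells by competing for the sodium iodide symporter, and a diet poor in iodine limits the same step from the supply side. The design text asks what the diet did over about 2 months, what perchlorate did over 1 or 14 days, and how the effects compare. Each value is the intensity of a probe set, on a log2 scale after adding 16, and each fold change is the difference of group means of 3 arrays each. A ± after a group mean is the SD (n = 3).

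Pearson correlations over probe sets between arrays of 1 group ran from 0.851 to 0.98 (median 0.973), and 0 pairs of arrays held identical values. Perchlorate replicate 18 of day 1 stood apart: the median absolute deviation of its genes from the median of the other arrays was 0.993, against 0.180 to 0.40 in the other 23 arrays. The next was control replicate 22 of day 1, at 0.40, and the other 22 arrays lay between 0.180 and 0.293. In replicate 18 the lymphocyte markers stood 3.31 above and the skeletal muscle markers 2.42 above the median of the other arrays. Genes with a long genomic span were lower in it, with a correlation across genes of -0.453 against -0.234 to 0.173 in the others. Both arrays were kept, and counts without them stand beside those below.

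**Figure D1:**
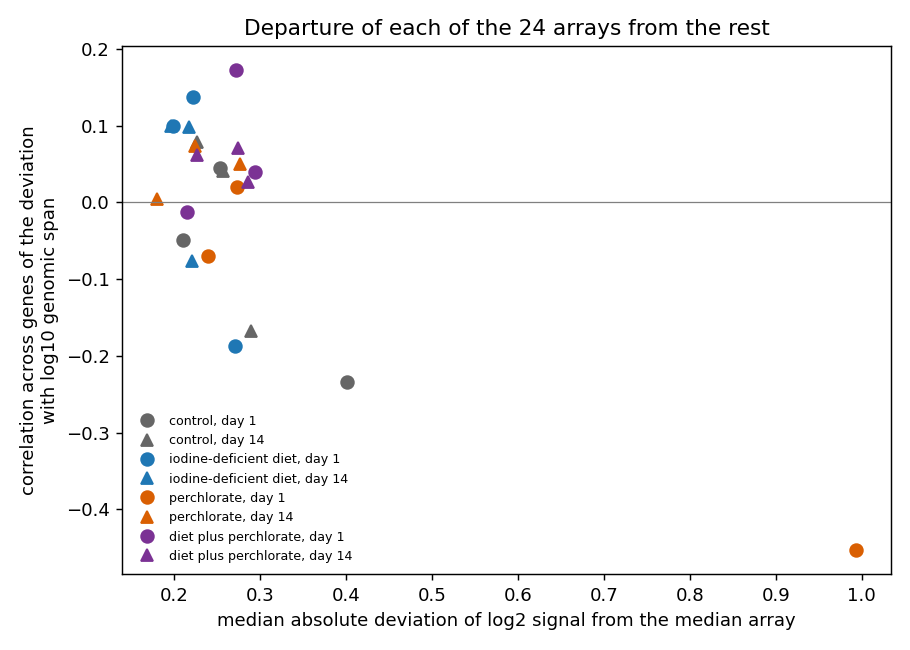
Each point is 1 of the 24 arrays. The horizontal axis is the median absolute deviation (log2) of its genes from the median of the other arrays. The vertical axis is the correlation across genes of that deviation with log10 of the genomic span, and perchlorate replicate 18 of day 1 lies alone at 0.993 and -0.453.

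The deficient diet at day 1, after 2 months of feeding, was compared with its control. The sodium iodide symporter gene Slc5a5, whose product brings iodide into follicular cells, rose by 1.22 (SE 0.19, adjusted p = 0.0174), from 10.82 ± 0.24 in controls to 12.03 ± 0.27. That call ended in a fit of only these groups (adjusted p = 0.234) and without diet replicate 8 (0.102) or 9 (0.111) or control replicate 21 (0.102) or 22 (0.0717), with log2 fold changes of 0.95 to 1.38 over the alternatives. Itih3, which encodes a heavy chain of the inter-alpha-trypsin inhibitor family that binds hyaluronan, rose by 2.18 (SE 0.28, adjusted p = 0.00276), a fold of 4.52. Sulf2, an enzyme that removes sulfate from heparan sulfate, rose by 0.76, and Mab21l3, Slc26a10 and Dlg5 rose by 1.24, 1.23 and 1.04. Igsf8 fell by 1.20 and C13h1orf116 fell by 1.21. Of the calls named here only that of Itih3 held under all 13 alternatives. Thyroglobulin (Tg), the protein on which thyroid hormone is made, differed by 0.03 (adjusted p = 0.998), and the thyrotropin receptor Tshr by 0.28 (adjusted p = 0.983). Of the 14 measured members of the list of hormone synthesis and iodide handling, 1 was called, Slc5a5.

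At this time 6 of the 24 lists stood above other genes by camera and 3 below, all with few or no called members. The cell cycle list had a median log2 fold change of 0.35 (0 of 45 members called, adjusted p = 3.55e-06) and the endothelial markers 0.36 (0 of 15, adjusted p = 0.000158). The median was 0.09 for endoplasmic reticulum folding (0 of 31, with 3 called when adjusted over the list alone, adjusted p = 0.000752). Adipocyte markers had a median of -0.90 (0 of 13, adjusted p = 1.38e-06), and skeletal muscle markers -1.37 (0 of 15, adjusted p = 0.00161). With an estimated correlation 0 lists were called, and the adjusted p of these 5 was 0.541 or 0.552 with an estimated correlation. With perchlorate at day 14 the muscle median was 0.42 against the day 14 controls but -1.48 against those of day 1. For adipocyte markers these values were -0.57 and -1.64. The muscle and adipocyte falls thus cannot be told apart from high values in the day 1 controls. The angiogenesis, lysosome, basement membrane and C cell lists were called too (medians 0.15, 0.08, 0.21 and -0.37), and all 4 lost the call without the 2 arrays that stood apart (adjusted p = 0.107, 0.0889, 0.107 and 0.0837). In all, limma called 10 probe sets, 8 higher and 2 lower, against 9 higher and 0 lower on the values as deposited. Without the 2 arrays 25 were called, and 2 in a fit of only these groups. Leaving out diet replicate 9 or control replicate 21 left 1, diet replicate 8 left 2, diet replicate 12 or control replicate 22 left 3, and control replicate 24 left 6.

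The deficient diet at day 14 was set against the control of that day. Itih3 rose by 3.81 (SE 0.28, adjusted p = 1.45e-07), a fold of 14.0, and Aspg, an asparaginase gene, rose by 3.55 (SE 0.36, adjusted p = 1.7e-05). Slc5a5 rose by 1.01 (SE 0.19, adjusted p = 0.0269), from 10.95 ± 0.30 to 11.96 ± 0.24, and that call ended without diet replicate 32 (adjusted p = 0.0769) or 33 (0.188) or control replicate 44 (0.145) or 47 (0.0833). The water channel gene Aqp1 rose by 1.80 and fibrillin 1, Fbn1, by 1.19, each on 1 of 2 probe sets. Vwa1, Srpx2 and Sema3g rose by 1.57, 1.31 and 1.26. Pde4b, a phosphodiesterase that degrades cAMP, rose by 0.79. The falls were Lamb3, a laminin chain of epithelial basement membrane (-1.44), C13h1orf116 (-1.32), Polr1b, a subunit of RNA polymerase I (-0.89), and ezrin, Ezr (-0.74). The calls of Itih3 and Aspg held under all 13 alternatives, and each other call named here was lost under 1 to 8 of them. Tg (-0.10, adjusted p = 0.89), Tshr (-0.35, adjusted p = 0.842) and the deiodinase gene Dio1 (1.21, adjusted p = 0.343) did not pass the test.

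Cell cycle genes stood above other genes as a list, with a median of 0.995 and an adjusted p = 4.28e-22. Of 45 members 0 were called over all probe sets and 24 when adjusted over the list alone. The mitotic phosphatase gene Cdkn3 was at 1.72 (adjusted p = 0.0515). Macrophage and mast cell markers (median 0.71, 0 of 18 called, 9 adjusted over the list alone) and endothelial markers (0.60, 0 of 15, 8 over the list alone) also stood above. So did extracellular matrix (0.58, 1 of 27, 7 over the list alone), basement membrane (0.61, 0 of 12, 6 over the list alone) and angiogenesis (0.50, 0 of 20, 5 over the list alone). The adjusted p of these 5 lay between 8.13e-11 and 4.48e-06. Ribosome biogenesis (-0.31, 1 of 29 called, adjusted p = 6.17e-07), C cell markers (-0.88, 0 of 13, adjusted p = 0.00102) and parathyroid markers (-1.115, 0 of 4, adjusted p = 0.00363) stood below. Glycolysis was lower too (-0.22, 0 of 18, adjusted p = 0.0215), and lysosome higher (0.15, 0 of 23, adjusted p = 0.0361). None of these calls held: the lowest was adjusted p = 0.139 with an estimated correlation. By fry 5 lists were called: cell cycle, angiogenesis, endothelium, ribosome biogenesis and glycolysis, each at an adjusted p between 0.0471 and 0.0497. limma called 41 probe sets, 36 higher and 5 lower, and 51 higher and 2 lower on the values as deposited, where the median of all probe sets moved to 0.132. The count was 221 without the 2 arrays of day 1, which changes the shared estimate of the spread, and 518 in a fit of only these groups. Leaving out diet replicates 32, 33 and 34 in turn left 10, 6 and 21, and control replicates 43, 44 and 47 left 17, 10 and 9.

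Over the mean of both days, the diet effect rested on 6 arrays against 6. Slc5a5 rose by 1.11 (SE 0.13, adjusted p = 9.21e-05), Itih3 by 2.99 (SE 0.20, adjusted p = 1.9e-08), Aspg by 2.53, and Uroc1, the urocanase gene of histidine breakdown, by 2.16. In the angiogenesis list 2 of 20 genes rose, apelin, Apln (1.42, on 1 of 2 probe sets), and Angpt2 (0.98), which encodes a ligand of the endothelial receptor Tie2. Of 15 endothelial markers 1 rose, Clec14a (0.84), and Cd93, in none of the lists, rose by 1.40. In the matrix list 2 of 27 rose, Fbn1 (0.86) and Col5a2 (0.68), and in the basement membrane list 2 of 12, Nid2 (0.70) and Lamb1 (0.69). In the lysosome list 2 of 23 rose, the cathepsin genes Ctss (0.76) and Ctsh (0.58). The kidney and thyroid cadherin Cdh16 rose by 0.63 and the macrophage scavenger receptor Cd163 by 0.95. Stra6, the receptor for retinol uptake, fell by 1.96 on its representative probe set and was called on 3 of 4. Angpt4 fell by 1.48, Gprc5a by 1.43, Krt19 by 1.02 and Lamb3 by 1.02. Nqo1, a quinone reductase induced by oxidative stress, fell by 0.86, and the neuroendocrine genes Uchl1 and Pcsk1n fell by 0.96 and 0.91. The calls of Slc5a5, Itih3, Aspg, Uroc1, Angpt4 and Lamb3 held under all 19 alternatives. Each other call named here, those of the vessel, matrix, basement membrane and lysosome genes included, was lost under 5 to 15 of them, with a highest adjusted p between 0.0619 (Fbn1) and 0.159 (Cdh16). Tg (-0.04, adjusted p = 0.916), Tshr (-0.03, adjusted p = 0.974) and Dio1 (0.94, adjusted p = 0.202) did not pass.

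The lists called for the mean of both days were cell cycle (median 0.61, 1 of 45 called, 24 adjusted over the list alone) and endothelium (0.52, 1 of 15, 10 over the list alone) on the higher side. With them were basement membrane (0.44, 2 of 12), angiogenesis (0.34, 2 of 20), macrophages (0.30, 1 of 18), matrix (0.29, 2 of 27) and lysosome (0.12, 2 of 23). On the lower side were C cells (-0.56, 1 of 13), adipocytes (-0.49, 0 of 13) and ribosome biogenesis (-0.19, 1 of 29). Their adjusted p ran from 3.32e-19 to 0.00744, and 0 held, with a lowest adjusted p = 0.211 with an estimated correlation. The adipocyte median was -0.90 at day 1 and -0.09 at day 14, so that call rests mostly on day 1 and its controls. limma called 191 probe sets, 149 higher and 42 lower (255 and 10 as deposited). The count was 406 without the 2 arrays that stood apart and 546 in a fit of only these groups. Leaving out day 1 diet replicates 9 and 12 left 86 and 69, and day 1 control replicates 21 and 22 left 97 and 94. Without day 14 diet replicates 32 and 33 it was 74 and 54, and day 14 control replicates 43, 44 and 47 left 96, 68 and 96.

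After 1 day of perchlorate no gene passed the test. Slc5a5 stood at 11.89 ± 0.35 against 10.82 ± 0.24 in controls, a log2 fold change of 1.07 (SE 0.19, adjusted p = 0.156) with no overlap between the 3 arrays of each group. Itih3 was at 0.26 (adjusted p = 0.718), Tg at 0.05 (adjusted p = 0.849) and Tshr at 0.17 (adjusted p = 0.831). Egr2, an immediate early transcription factor gene, was at 1.12 (adjusted p = 0.284), Nqo1 at -1.09 and Gclc, a subunit of the enzyme that limits glutathione synthesis, at -0.77 (adjusted p = 0.423 for both). limma called 0 of 18625 probe sets, with 1888 at an unadjusted p under 0.05. It also called 0 without the 2 arrays that stood apart, 1 in a fit of only these groups, 12 with array quality weights, 55 without perchlorate replicate 16 and 2 without perchlorate replicate 15.

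Of the lists, lymphocyte markers stood above other genes at day 1 of perchlorate (median 2.60, 0 of 3 called, 3 adjusted over the list alone, adjusted p = 0.00342, and adjusted p = 0.535 with an estimated correlation). They varied widely between the arrays: Cd3d, a chain of the T cell receptor complex, was at 8.92 ± 2.53 against 5.88 ± 0.29. Skeletal muscle markers stood below (median -1.86, 0 of 15, adjusted p = 0.00342, and adjusted p = 0.89 with an estimated correlation), with troponin C gene Tnnc2 at 7.29 ± 2.81 against 10.89 ± 1.77. This fall cannot be told apart from high values in the same day 1 controls. The cell cycle list had a median of 0.22 (0 of 45, adjusted p = 0.0156, and adjusted p = 0.964 with an estimated correlation). Of the hormone synthesis list 13 of 14 members had a positive fold change (median 0.17), which camera did not call (adjusted p = 0.111) and fry did (adjusted p = 0.0359). On the values as deposited camera did call it higher (adjusted p = 0.026), with mitochondrial phosphorylation higher (0.0133) and ribosome biogenesis lower (0.0436). At the main settings these 3 lists had an adjusted p = 0.535, 0.964 and 0.89 with an estimated correlation. With the mean of all probe sets of a gene, immediate early genes were called higher (adjusted p = 0.0319). At the main settings that list was not called (adjusted p = 0.111, and adjusted p = 0.89 with an estimated correlation). Without the 2 arrays that stood apart, ribosome biogenesis (adjusted p = 0.0114) and macrophages (adjusted p = 0.0107) were called lower, and the C cell markers, not called with all arrays (adjusted p = 0.92), were called higher (adjusted p = 0.0147). All 3 of these calls were lost, at adjusted p = 0.757 with an estimated correlation.

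After 14 days of perchlorate the thyroid differed widely from its control. Itih3 rose by 5.40 (SE 0.28, adjusted p = 1.57e-10), from 7.23 ± 0.04 to 12.62 ± 0.44, a fold of 42.1. Slc5a5 rose by 1.52 (SE 0.19, adjusted p = 8e-05), from 10.95 ± 0.30 to 12.46 ± 0.17, a fold of 2.86. It was the only one of the 14 measured members of the hormone synthesis list to be called. Tg (0.05, adjusted p = 0.913), Tshr (0.13, adjusted p = 0.941) and Dio1 (0.52, adjusted p = 0.736) did not pass, nor did the dual oxidase gene Duox2 (-0.29, adjusted p = 0.655) and the iodotyrosine deiodinase gene Iyd (0.14, adjusted p = 0.744). Aspg rose by 3.55, Smtnl2 by 2.75, Mab21l3 by 2.61, Vwa1 by 2.44 and Ninl by 2.42. The largest falls were those of the antimicrobial peptide gene Defb1 (-3.28, SE 0.43), Tmem213 (-3.24) and Stra6 (-3.01, lower on 3 of 4 probe sets). C13h1orf116 fell by 2.30, the lactate transporter gene Slc16a3 by 2.28 and Aldh1a3, which makes retinoic acid from retinaldehyde, by 1.83, a call lost under 4 of 13 alternatives.

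**Figure D2:**
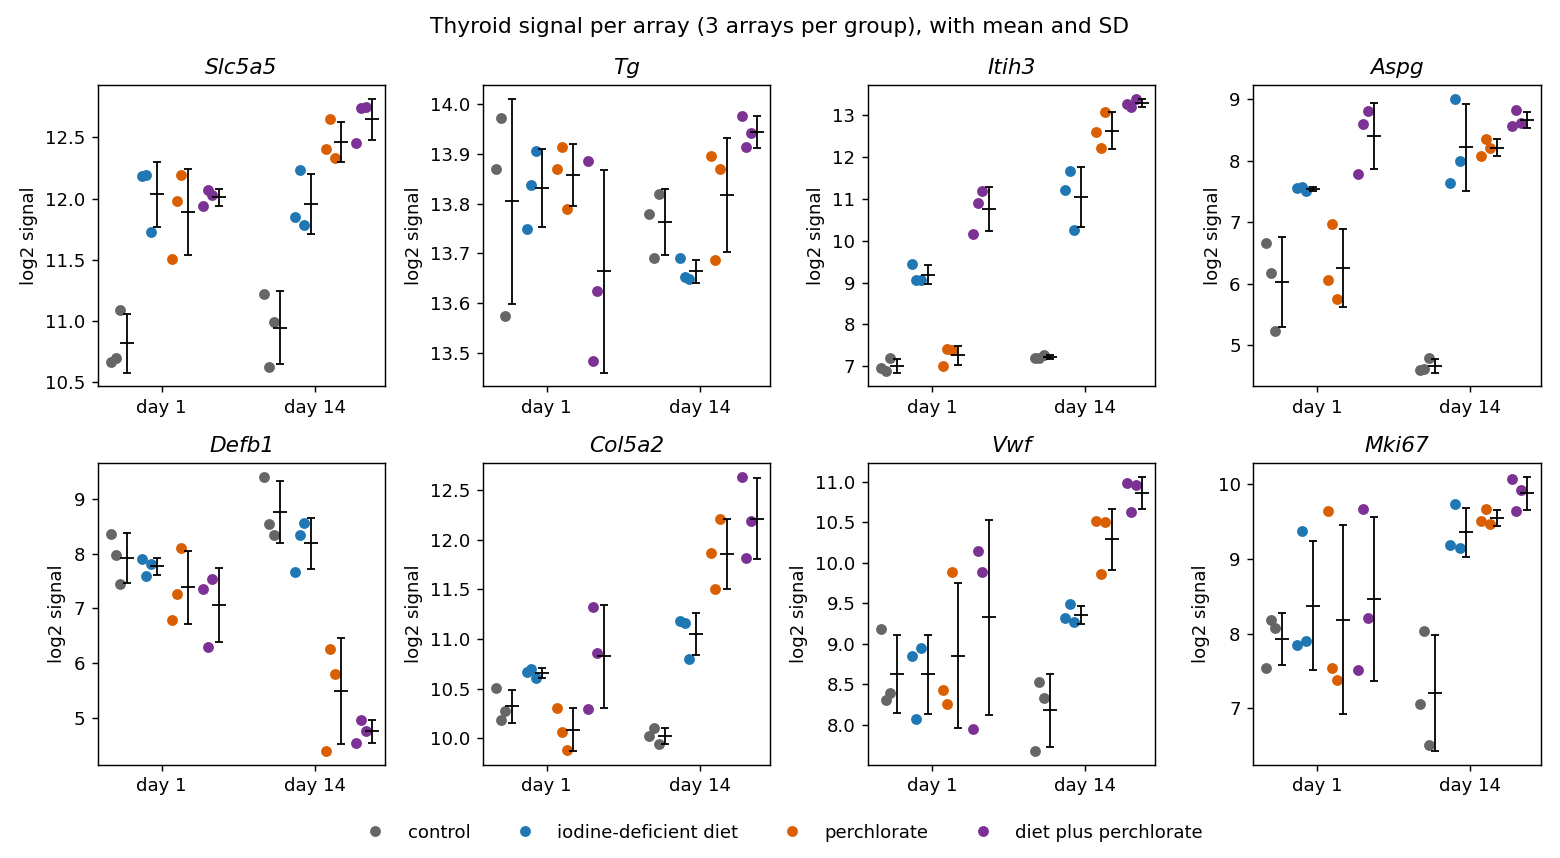
Each panel shows 1 gene's log2 signal on every array (points) with the group mean and SD (bars, n = 3) for control, perchlorate, diet and diet with perchlorate at day 1 and day 14. Itih3 is at 7.23 in day 14 controls and 12.62 with perchlorate, Slc5a5 at 10.95 and 12.46, while Tg is at 13.76 and 13.82.

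Genes of dividing cells rose with 14 days of perchlorate. Of 45 measured cell cycle genes 13 were called higher and 0 lower (29 adjusted over the list alone), with a median of 1.02. Among them were the proliferation marker Mki67 (2.35, SE 0.54, adjusted p = 0.0158), cyclin A2, Ccna2 (2.01), Melk (1.87) and Cdkn3 (1.66). Matrix genes rose as well, 15 of 27 in the list (20 over the list alone, median 1.09), with Col5a3 (2.63), Fbn1 (1.89), Col5a2 (1.83) and the collagen crosslinking enzyme gene Loxl2 (1.49). In the basement membrane list 8 of 12 rose (10 over the list alone, median 1.15), with nidogens Nid2 (1.80) and Nid1 (1.75, 1 of 2 probe sets) and type IV collagens Col4a2 (1.55) and Col4a1 (1.54). Vessel genes rose, 7 of 15 endothelial markers (14 over the list alone, median 0.87) and 5 of 20 angiogenesis genes (12 higher and 1 lower over the list alone, median 0.70). Among these were Apln (2.50), von Willebrand factor, Vwf (2.12), Angpt2 (2.11) and endoglin, Eng (1.83). Of 18 macrophage and mast cell markers 5 rose (14 over the list alone, median 0.87), with the mast cell tryptase gene Tpsab1 (2.26), the mannose receptor gene Mrc1 (1.13) and Aif1 (1.12). The adjusted p of these 6 lists ran from 1.2e-20 to 1.32e-08. All 6 calls were lost, with an adjusted p = 0.0503 with an estimated correlation for matrix, basement membrane and endothelium. For angiogenesis it was adjusted p = 0.0508 with an estimated correlation, and for cell cycle and macrophages adjusted p = 0.122 with an estimated correlation. By fry all 6 were called. The calls of Mki67, Ccna2, Melk, Cdkn3, Col5a3, Vwf, Tpsab1, Mrc1 and Aif1 were each lost under 1 to 6 of 13 alternatives.

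Immediate early and cAMP-responsive genes had a median of 0.32 (2 of 27 called, Pde4b at 1.31 and Atf3 at 1.13, adjusted p = 0.002). Cartilage markers had a median of 0.76 (2 of 5, Col11a1 at 1.61 and Col9a3 at 0.79, adjusted p = 0.0247) and lysosome 0.10 (2 of 23, Ctss at 1.15 and Ctsh at 0.97, adjusted p = 0.0247). Each of these 3 had an adjusted p = 0.122 with an estimated correlation. On the lower side was ribosome biogenesis (median -0.35, adjusted p = 9.08e-05, and adjusted p = 0.122 with an estimated correlation), with Polr1b lower at -0.73 and Rrp1b higher at 1.26 on 1 of 2 probe sets. Glycolysis was lower (median -0.21, 1 of 18 lower, Slc16a3, adjusted p = 0.00161, and adjusted p = 0.0503 with an estimated correlation). Endoplasmic reticulum folding was called lower too (median -0.18, 0 of 31, adjusted p = 0.00223, and adjusted p = 0.232 with an estimated correlation). In antioxidant defence 2 of 26 fell, Nqo1 at -1.48 and Gclc at -1.14 (median -0.12, adjusted p = 0.00677, and adjusted p = 0.356 with an estimated correlation). Hormone synthesis (median 0.06, adjusted p = 0.826) and thyroid transcription factors (-0.05, 1 of 11 higher, Cdh16 at 1.00, adjusted p = 0.819) were not called. Neither were thyroid hormone responsive genes (-0.13, 0 of 15, adjusted p = 0.819), mitochondrial phosphorylation (-0.07, 0 of 40, adjusted p = 0.077) or cholesterol synthesis (-0.25, 1 of 20 higher, adjusted p = 0.163). The calls of Atf3, Col9a3, Ctss, Polr1b and Cdh16 were each lost under 1 to 8 of 13 alternatives.

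All 13 C cell and neuroendocrine markers had a negative fold change at day 14 of perchlorate (median -0.79, 0 called, adjusted p = 0.000264, and adjusted p = 0.232 with an estimated correlation). Of the 4 parathyroid markers 2 fell, the calcium-sensing receptor gene Casr (-1.56) and klotho, Kl (-1.70), calls lost under 7 and 4 of 13 alternatives. Their median was -1.63 (adjusted p = 0.000794, and adjusted p = 0.122 with an estimated correlation), while parathyroid hormone, Pth, was at 13.81 against 14.01 (adjusted p = 0.616). Against the day 1 controls the parathyroid median was -0.23. Muscle (median 0.42, adjusted p = 0.58), adipocyte (-0.57, adjusted p = 0.109), lymphocyte (0.90, adjusted p = 0.311) and red blood cell markers (0.00, adjusted p = 0.891) were not called. limma called 665 probe sets, 540 higher and 125 lower. The count was 1426 without the 2 day 1 arrays that stood apart (all 665 among them) and 1244 in a fit of only these groups. Leaving out perchlorate replicates 39 and 42 left 298 and 225, and control replicates 43, 44 and 47 left 326, 363 and 387.

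**Figure D3:**
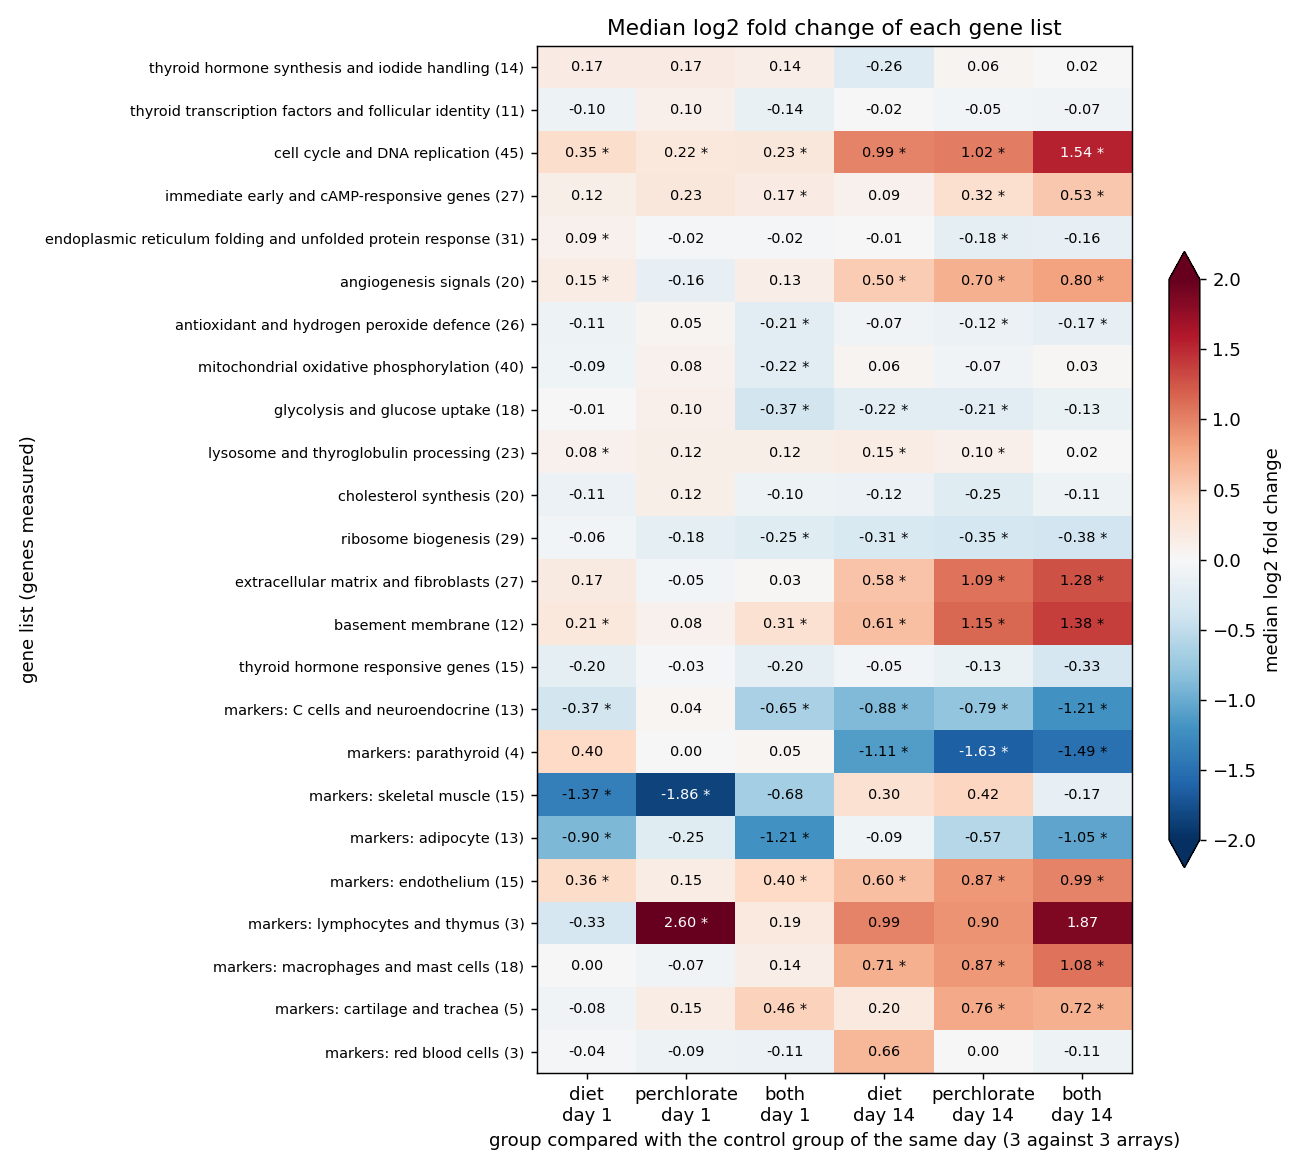
Median log2 fold change of the measured members of each of the 24 gene lists (rows) in the 6 comparisons with the control of the same day (columns). An asterisk marks an adjusted p under 0.05 by camera at the preset correlation, and with perchlorate at day 14 the medians are 1.15 for basement membrane, 1.09 for matrix and -0.79 for C cell markers.

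The diet with 1 day of perchlorate was set against the day 1 control. Itih3 rose by 3.74 (SE 0.28, adjusted p = 2.05e-07), Uroc1 by 3.47 (SE 0.52, adjusted p = 0.00201) and Aspg by 2.38. Pde1a rose by 2.20, the opioid receptor gene Oprk1 by 2.20 on 1 of 2 probe sets, Card9 by 2.04 and Ptpn22 by 1.96. Slc5a5 rose by 1.19 (SE 0.19, adjusted p = 0.00262), from 10.82 ± 0.24 to 12.01 ± 0.07, and Pde4b by 1.08. Esm1, an endothelial proteoglycan gene, fell by 2.28, and the antioxidant genes Nqo1 and Gclc fell by 1.82 and 0.96. The circadian clock genes Nr1d1 and Dbp fell by 1.54 (adjusted p = 0.00421) and 1.11 (adjusted p = 0.0105). Both calls ended in a fit of only these groups (adjusted p = 0.0545 and 0.0756), and that of Dbp also without treated replicate 3 (0.051) or control replicate 21 (0.0704). The calls of Aspg, Pde1a, Oprk1, Pde4b and Gclc were each lost under 1 to 8 of 13 alternatives. Day 14 minus day 1 in the untreated controls, which uses the same day 1 arrays, gave -1.44 and -1.09 for them, where limma called 0 probe sets, with 765 at an unadjusted p under 0.05. Tg (-0.14, adjusted p = 0.67) and Tshr (0.63, adjusted p = 0.462) did not pass.

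Glycolysis and glucose uptake genes stood below others in this comparison, with a median of -0.37 (adjusted p = 0.000121), and this call held (adjusted p = 0.0359 with an estimated correlation). Of 18 members 0 were called over all probe sets, and 9 lower and 2 higher when adjusted over the list alone. Aldolase A, Aldoa, was at -0.50 (adjusted p = 0.088) and lactate dehydrogenase A, Ldha, at -0.32 (adjusted p = 0.094). Also lower were adipocyte markers (median -1.21, 0 of 13), mitochondrial phosphorylation (-0.22, 0 of 40), C cell markers (-0.65, 0 of 13), ribosome biogenesis (-0.25, 0 of 29) and antioxidant defence (-0.21, 2 of 26). Higher were endothelium (0.40, 0 of 15), basement membrane (0.31, 0 of 12), cartilage (0.46, 1 of 5), cell cycle (0.23, 0 of 45) and immediate early genes (0.17, 1 of 27). These 10 calls were lost, with a lowest adjusted p = 0.228 with an estimated correlation. Among the 10, fry called only cartilage (adjusted p = 0.0413). The adipocyte fall rests on the same day 1 controls, which may be high in fat. Without the 2 arrays that stood apart, the cell cycle (adjusted p = 0.111), immediate early (0.0585), antioxidant (0.0646), basement membrane (0.0554) and cartilage (0.0585) calls ended too. limma called 112 probe sets, 83 higher and 29 lower (180 and 10 as deposited, where the median of all probe sets moved to 0.203). The count was 341 without the 2 arrays and 19 in a fit of only these groups. Leaving out replicate 3 or 6 of the treated group left 60, and control replicate 21 left 66.

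The diet with 14 days of perchlorate gave the largest count of called probe sets among the comparisons with a control. Itih3 rose by 6.06 (SE 0.28, adjusted p = 1.52e-11), from 7.23 ± 0.04 to 13.28 ± 0.10, a fold of 66.6. Uroc1 rose by 4.02, Aspg by 3.99, Smtnl2 by 3.62 and macrophage elastase, Mmp12, by 3.25. Crym, a cytosolic protein that binds thyroid hormone, rose by 3.01, Cthrc1 by 2.98 and the somatostatin receptor gene Sstr1 by 2.94. Slc5a5 rose by 1.70 (SE 0.19, adjusted p = 1.12e-05), from 10.95 ± 0.30 to 12.65 ± 0.17. Tg (0.18, adjusted p = 0.317), Tshr (0.00, adjusted p = 0.996) and Duox2 (-0.39, adjusted p = 0.319) did not pass. Defb1 fell by 4.01 (SE 0.43), Stra6 by 3.35 on 4 of 4 probe sets, Slc16a3 by 2.57, Aldh1a3 by 2.48, C13h1orf116 by 2.16 and Shmt1, an enzyme of folate metabolism, by 1.87. Foxe1, a transcription factor of thyroid identity, fell by 0.51 and the junction gene Cldn3 by 0.90, calls lost under 5 and 7 of 13 alternatives, while Cdh16 rose by 1.24. The list of thyroid transcription factors was not called (median -0.07, adjusted p = 0.79).

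Of the 45 cell cycle genes 34 rose and 0 fell (42 adjusted over the list alone, median 1.54, adjusted p = 2.64e-26), with Ccna2 at 2.50, Melk at 2.45 and Cdk1 at 2.12. Matrix rose in 19 of 27 members (median 1.28), with lysyl oxidase, Lox, at 1.94 and biglycan, Bgn, at 1.83, and basement membrane in 9 of 12 (median 1.38). Endothelium rose in 9 of 15 (median 0.99), with Vwf at 2.69 and Sox18 at 1.595, and angiogenesis in 10 of 20 (median 0.80), with Apln at 3.04. Immediate early genes rose in 6 of 27 (median 0.53), with Atf3 at 1.41 and Egr2 at 1.27, and macrophages in 11 of 18 (median 1.08), with the Fc receptor gene Fcgr1a at 1.58. These 7 calls were lost: adjusted p = 0.084 with an estimated correlation for macrophages and adjusted p = 0.0706 with an estimated correlation for each of the others. By fry all 7 were called. C cell and neuroendocrine markers fell in 6 of 13 members and all 13 were below 0 (median -1.21, adjusted p = 1.31e-06, and adjusted p = 0.14 with an estimated correlation). Among them were secretogranin II, Scg2, at -2.15 and the calcitonin gene-related peptide gene Calcb at -1.93. Parathyroid markers fell in 2 of 4, Casr (-1.81) and Kl (-1.51) (median -1.485, adjusted p = 0.00372, and adjusted p = 0.174 with an estimated correlation). Cartilage (median 0.72, 3 of 5) was called higher. Ribosome biogenesis (-0.38, 4 of 29 lower and 1 higher), antioxidant defence (-0.17, 3 of 26) and adipocyte markers (-1.05, 0 of 13) were called lower, and these 4 had a lowest adjusted p = 0.137 with an estimated correlation. Of the 15 thyroid hormone responsive genes 3 fell, Thrsp (-1.27, 3 of 3 probe sets), Hr (-0.83) and Klf9 (-0.53), and the list was not called (adjusted p = 0.1). The calls of Thrsp and Hr ended without treated replicate 30 or control replicate 43 or 44 (highest adjusted p = 0.14 and 0.125). That of Klf9 ended on the values as deposited and without treated replicate 27, 29 or 30 or control replicate 44 or 47 (highest adjusted p = 0.207), and those of Scg2, Casr and Kl under 3, 1 and 4 of 13 alternatives. limma called 1649 probe sets, 1137 higher and 512 lower (915 and 248 as deposited). The count was 3295 without the 2 day 1 arrays and 3199 in a fit of only these groups. Leaving out treated replicates 27 and 30 left 808 and 922, and control replicates 43, 44 and 47 left 1035, 1020 and 1097.

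On the deficient diet, adding perchlorate for 1 day changed 1 gene. Mta1, a subunit of a chromatin remodelling complex, fell by 1.57 (SE 0.21, adjusted p = 0.00473), from 6.90 ± 0.18 to 5.33 ± 0.33. Slc5a5 differed by -0.02 (adjusted p = 0.999) and Tg by -0.17 (adjusted p = 0.94). Glycolysis genes stood below others (median -0.22, 0 of 18 called and 2 lower adjusted over the list alone, adjusted p = 5.09e-05, and adjusted p = 0.0216 with an estimated correlation). Endoplasmic reticulum folding (-0.13), mitochondrial phosphorylation (-0.17), ribosome biogenesis (-0.20) and antioxidant defence (-0.10) were called lower and cartilage higher (0.49), and all 5 were lost (lowest adjusted p = 0.146 with an estimated correlation). The count was 62 without the 2 arrays that stood apart, 0 in a fit of only these groups or without treated replicate 3 or diet replicate 8, 2 without treated replicate 2 and 3 without diet replicate 12. At the main settings 1087 probe sets had an unadjusted p under 0.05.

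On the deficient diet, adding perchlorate for 14 days raised Itih3 further, by 2.25 (SE 0.28, adjusted p = 0.000825). Crym (2.80), Cthrc1 (2.35), Sstr1 (2.14), Ccn5 (1.69), the BMP antagonist gene Grem1 (1.56) and Col5a2 (1.16) rose. So did the growth factor binding protein gene Igfbp3 (1.81, 1 of 2 probe sets), Lox (1.32, 1 of 2) and the chemokine receptor gene Cxcr4 (1.28, 3 of 3). Defb1 fell by 3.45 (SE 0.43, adjusted p = 0.000825), Gna14 by 1.61, Cxcl14 by 1.51, Shmt1 by 1.40, Selenbp1 by 1.40 and Hlf by 1.27. Of these calls only those of Itih3 and Defb1 held under all 13 alternatives. Slc5a5 was at 0.69 (adjusted p = 0.161) and Tg at 0.28 (adjusted p = 0.391). Matrix (median 0.74, 2 of 27 called, 18 over the list alone) and basement membrane (0.65, 0 of 12, 8 over the list alone) were called higher. So were cell cycle (0.53, 0 of 45), macrophages (0.54, 0 of 18), endothelium (0.36, 0 of 15), immediate early genes (0.29, 0 of 27) and angiogenesis (0.21, 0 of 20). Lower were the adipocyte (-0.77), red blood cell (-0.78), C cell (-0.54), thyroid hormone responsive (-0.37), antioxidant (-0.10) and endoplasmic reticulum (-0.10) lists. All 13 were lost, with a lowest adjusted p = 0.0664 with an estimated correlation. By fry 3 of the 13 were called, immediate early genes, matrix and basement membrane (adjusted p = 0.0244, 0.0339 and 0.0463). limma called 39 probe sets, 24 higher and 15 lower (7 and 16 as deposited, where the median of all probe sets moved to -0.148). The count was 173 without the 2 day 1 arrays and 338 in a fit of only these groups. Leaving out treated replicates 27 and 30 left 3 each, and diet replicates 32 and 34 left 2 and 3.

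The diet and perchlorate were also set against each other directly, as the series title asks. At day 1 Itih3 was higher with the diet than with perchlorate by 1.92 (SE 0.28, adjusted p = 0.0191), 9.19 ± 0.22 against 7.27 ± 0.23. Slc5a5 differed by 0.14 (adjusted p = 0.682). Lymphocyte markers were lower with the diet (median -2.93, 0 of 3 called and 3 adjusted over the list alone, adjusted p = 0.0122, and adjusted p = 0.787 with an estimated correlation), beside the high values of perchlorate replicate 18. Angiogenesis (0.31) and endoplasmic reticulum folding (0.18) were called higher and adipocyte markers (-0.78) and mitochondrial phosphorylation (-0.20) lower, each at adjusted p = 0.787 with an estimated correlation. limma called 2 probe sets, that of Itih3 and 1 with no symbol, against 0 without the 2 arrays that stood apart and 2 others in a fit of only these groups. Leaving out perchlorate replicates 15, 16 and 18 left 358, 408 and 0, and diet replicates 8 and 12 left 0 each.

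At day 14 Defb1 was higher with the diet than with perchlorate by 2.71 (SE 0.43, adjusted p = 0.0467), 8.19 ± 0.47 against 5.48 ± 0.97, and it was the only probe set called. Slc5a5 differed by -0.51 (adjusted p = 0.999), Col5a2 by -0.81 (adjusted p = 0.662) and Fbn1 by -0.70 (adjusted p = 0.999). As lists, matrix (median -0.50, 0 of 27, 7 adjusted over the list alone, adjusted p = 5.15e-16) and basement membrane (-0.56, 0 of 12, 8 over the list alone, adjusted p = 7.2e-11) were lower with the diet, each with an adjusted p = 0.0998 with an estimated correlation. Red blood cell markers (0.44), adipocyte markers (0.26), mitochondrial phosphorylation (0.17), endoplasmic reticulum folding (0.14) and antioxidant defence (0.09) were called higher. Endothelium (-0.24), macrophages (-0.25), angiogenesis (-0.21) and immediate early genes (-0.18) were called lower, and these 9 had a lowest adjusted p = 0.283 with an estimated correlation. The Defb1 call ended with a pseudocount of 1 or 64, without the filter, in a fit of only these groups, and without diet replicate 32 or 34 or perchlorate replicate 39 or 42, each of which gave 0 calls. Without diet replicate 33 or without the 2 arrays of day 1, 2 probe sets were called, and at the main settings 693 probe sets had an unadjusted p under 0.05.

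The interaction asks whether perchlorate acted differently on the deficient diet. At day 1 Mta1 had an interaction of -1.97 (SE 0.30, adjusted p = 0.0274) and the glypican gene Gpc4 of 1.47 (SE 0.24, adjusted p = 0.0392). Gpc4 was at 11.42 ± 0.19 in controls and 10.51 ± 0.18 with perchlorate, against 11.10 ± 0.32 and 11.67 ± 0.19 on the diet. Glycolysis (-0.32), mitochondrial phosphorylation (-0.26), cell cycle (-0.34) and muscle (2.485) were called as lists and all lost (lowest adjusted p = 0.132 with an estimated correlation). By fry glycolysis alone was called (adjusted p = 0.0285). The muscle value takes in the day 1 controls, which may be high in muscle. The 2 calls ended, with 0 left, on the values as deposited, without the filter, in a fit of only these groups and without the 2 arrays that stood apart. Leaving out any 1 control, treated replicate 2 or 3 or diet replicate 8 also left 0, treated replicate 6 or perchlorate replicate 15 left 1, and perchlorate replicate 18 left 5.

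At day 14 the interaction was negative for Itih3 (-3.15, SE 0.40, adjusted p = 0.00195), Aspg (-3.10, SE 0.50, adjusted p = 0.036) and Mab21l3 (-1.72, SE 0.29, adjusted p = 0.0426). On the log2 scale the rise with perchlorate was smaller for each on the diet than on normal food. The diet alone had already raised Itih3, Aspg and Mab21l3, and a smaller fold need not be a smaller gain in signal units. Aspg was at 4.67 ± 0.11 in controls, 8.22 ± 0.14 with perchlorate, 8.22 ± 0.71 on the diet and 8.66 ± 0.14 with both. Slc5a5 had an interaction of -0.83 (SE 0.27, adjusted p = 1). Endothelial (-0.61), cell cycle (-0.45), matrix (-0.39), macrophage (-0.38), basement membrane (-0.33) and angiogenesis (-0.32) lists were called lower and glycolysis higher (0.23), with a lowest adjusted p = 0.0593 with an estimated correlation. Parathyroid markers were called higher (1.16) and red blood cell markers lower (-0.77), each at adjusted p = 0.32 with an estimated correlation. Mitochondrial phosphorylation (0.07) and ribosome biogenesis (0.19) were called higher too, at adjusted p = 0.725 and adjusted p = 0.32 with an estimated correlation. On the values as deposited the median of all probe sets moved to -0.221 and those of these 2 lists to -0.11 and -0.02, still above it, with adjusted p = 0.0537 and 0.00451. The count of 3 was 6 in a fit of only these groups and 1 with a pseudocount of 64, without the filter, or without any 1 of 9 arrays (treated replicates 29 and 30, diet 33 and 34, perchlorate 40 and 42, and each control).

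The perchlorate effect at day 14 lay above that at day 1 for 91 probe sets and below it for 12, 103 in all. Itih3 differed by 5.14 (SE 0.40, adjusted p = 3.54e-07), Aspg by 3.31, Smtnl2 by 3.12, RT1-T24-3 by 2.99, Cthrc1 by 2.56 and Srpx2 by 2.49. Angpt2 differed by 2.40, Col5a2 by 2.07, Fbn1 by 1.97, Nid2 by 1.80 and Mrc1 by 1.54. On the negative side were Defb1 (-2.74), Pax1 (-2.23), Lamb3 (-2.19), Rap1gap2 (-1.94), C13h1orf116 (-1.80) and Aplp1 (-1.60). The calls of Smtnl2, Cthrc1, Nid2, Mrc1, Defb1, Pax1, Rap1gap2 and Aplp1 were each lost under 1 to 14 of 19 alternatives. Slc5a5 differed by 0.44 (SE 0.27, adjusted p = 0.52). Matrix (median 0.98, 5 of 27 called, 14 over the list alone), basement membrane (0.98, 3 of 12) and macrophages (0.95, 1 of 18) were called higher. So were cell cycle (0.81, 0 of 45), endothelium (0.80, 0 of 15, 6 over the list alone) and angiogenesis (0.79, 1 of 20). Skeletal muscle markers had the largest median of the called lists, 2.31 (0 of 15, adjusted p = 0.00807), beside -1.86 with perchlorate at day 1. That value takes in the day 1 controls, which may be high in muscle. C cell markers (-0.65, 0 of 13), parathyroid markers (-1.47, 0 of 4), glycolysis (-0.36), endoplasmic reticulum folding (-0.25), antioxidant defence (-0.17) and mitochondrial phosphorylation (-0.16) were called lower. All 13 calls were lost, with a lowest adjusted p = 0.0979 with an estimated correlation. By fry 4 of the lists were called: matrix, angiogenesis and glycolysis (adjusted p = 0.0147 each) and basement membrane (0.0153). The count was 66 without the 2 arrays that stood apart (45 of them among the 103) and 32 in a fit of only these groups. Leaving out day 1 perchlorate replicates 15 and 18 left 317 and 180, day 1 control replicates 21, 22 and 24 left 56, 48 and 38, day 14 perchlorate replicates 39 and 42 left 34 and 30, and day 14 control replicates 43, 44 and 47 left 44, 37 and 56.

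For the diet, fed for about 2 months at both times, the effect at day 14 minus that at day 1 was added after seeing the data. It gave 0 calls by limma, with 502 probe sets at an unadjusted p under 0.05. The alternatives also gave 0, except 1 in a fit of only these groups. Of the lists 10 were called higher and 3 lower. Higher were skeletal muscle (median 1.72), adipocytes (0.84), red blood cells (0.81), cell cycle (0.68), macrophages (0.59), matrix (0.51), basement membrane (0.36), endothelium (0.34), angiogenesis (0.31) and mitochondrial phosphorylation (0.13). Lower were parathyroid markers (-1.46), ribosome biogenesis (-0.25) and endoplasmic reticulum folding (-0.12). All 13 were lost, with a lowest adjusted p = 0.303 with an estimated correlation. The muscle and adipocyte values take in the day 1 controls, which may be high in both tissues.

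The likeness of the diet and perchlorate effects was measured over all probe sets tested. At day 14 their log2 fold changes had a correlation of 0.800 across probe sets, against a median of 0.499 (-0.0423 to 0.827) for simulated unchanged groups sharing the same controls. The covariance was 0.112 against a simulated 0.0247 (0.000911 to 0.0471), a difference of 0.0876. Of 36 probe sets higher with the diet, 35 were among the 540 higher with perchlorate (1.04 by chance), and of 5 lower 4 were among the 125 (0.0336 by chance). At day 1 the correlation was 0.294, below the simulated median of 0.547 (-0.145 to 0.872), and the covariance of 0.0304 lay below the simulated 0.0554. The simulated groups drew day 1 arrays at random, so replicate 18 could fall among the shared controls, while in the data it is a perchlorate array. The day 1 values thus do not show that the effects were less alike than those of unchanged groups. Without perchlorate replicate 18 the correlation was 0.502, and without the 2 arrays that stood apart the correlation was 0.434, with no simulation to match. Between perchlorate alone and the diet with perchlorate at day 14 it was 0.886, against the same simulated median of 0.499 (-0.0423 to 0.827), with 513 of 540 higher calls shared (33 by chance) and 106 of 125 lower calls (3.44 by chance). These chance counts take the lists as independent, although both effects use the same 3 controls. Effects that share no array had correlations of 0.354 (diet, day 1 with day 14) and 0.0468 (perchlorate, day 1 with day 14). They were 0.294 for the diet at day 1 with perchlorate at day 14, 0.000488 for the diet at day 14 with perchlorate at day 1, and 0.486 for the diet with perchlorate between the days. The 3 controls of a day are too few to split, so part of the excess may come from the shared controls.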

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

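The counts of splits, the regrouping of residuals, the tests of explanations for the matrix, endothelium and macrophage lists, and the choice of genes among dim probe sets were chosen after the results were seen. The genes below were picked out because their perchlorate effects differed between diets or between days in a test of that difference. Splits that mix treatments widen the spread within groups, so the residuals left after the additive effects were also regrouped 100 times, the real grouping included.

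At day 1 the test of the difference between diets picked out 2 probe sets. Mta1, a chromatin remodelling subunit, had an interaction of -1.97, and the glypican gene Gpc4 one of 1.47. Of 100 splits of the same arrays, the real one included, 8 gave at least 2 calls, as did 12 of 100 regroupings of residuals, so chance cannot be excluded. The highest other split gave 603. It set all 3 controls against all 3 arrays with both treatments, so the structure it points to includes the treatment effects themselves. The highest regrouping of residuals gave 3937, which points to a structure of the samples that the groups do not follow.

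At day 14 the same test picked out 3 probe sets. The interaction was -3.15 for Itih3, -3.10 for Aspg and -1.72 for Mab21l3. The log2 fold change of each with perchlorate was thus smaller on the deficient diet than on normal food. Of 100 splits 2 gave at least 3 calls, and of 100 regroupings of residuals only the real one, with 2 in the highest other. That share is under 0.05, but 100 draws that include the real grouping give it only roughly, and 3 calls against 2 is a narrow gap. Chance is thus not firmly excluded for the count or for each gene, and the count was 1 without any 1 of 9 arrays. The calls of Aspg and Mab21l3 were lost under 13 and 15 of 19 alternatives, and that of Itih3 under 0. The other split gave 200 and again set all 3 controls against all 3 arrays with both treatments, so it too follows the treatment effects.

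Between day 14 and day 1 the perchlorate effect differed for 103 probe sets, and 1 of 100 splits, the real one, gave as many, with 56 in the highest other. Of 100 regroupings of residuals 3, the real one included, gave as many. That share is under 0.05, but 100 draws give it only roughly. The highest gave 2788, which again points to a structure of the samples. The residuals also hold the 2 day 1 arrays that stood apart, so chance is not firmly excluded for this count. The effect was larger at day 14 for Itih3 (5.14), Aspg (3.31), Smtnl2 (3.12), RT1-T24-3 (2.99), Cthrc1 (2.56) and Srpx2 (2.49). It was lower at day 14 for the antimicrobial peptide gene Defb1 (-2.74), Pax1 (-2.23), Lamb3 (-2.19), Rap1gap2 (-1.94), C13h1orf116 (-1.80) and Aplp1 (-1.60).

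Matrix, endothelium and macrophage lists were called higher with perchlorate at day 14 at the preset correlation (adjusted p = 0.0503, 0.0503 and 0.122 with an estimated correlation). The C cell markers had a median of -0.79 against 0.87 for endothelium, so the markers of the other cell types did not move alike. None of the 13 C cell markers was called, and that list had an adjusted p = 0.232 with an estimated correlation. This does not decide on a lower share of follicular cells, because the share of C cells may change on its own. Low values in the 3 day 14 controls as the cause are argued against by a matrix median of 0.89 against the day 1 controls. The order in which animals or arrays were handled cannot be told apart from the treatment, because sample numbers run by group and 0 pairs of groups interleave. An effect of perchlorate on stroma, vessels and macrophages stays a hypothesis.

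A few of the dim probe sets, left out of the comparisons by the filter on signal, differed from the day 14 controls. With no filter, limma called 38 of 12417 dim probe sets with perchlorate at day 14, 33 higher and 5 lower, and 27 of the 38 carry 1 symbol. Among them, chosen after their values were seen, C1qtnf3, a secreted protein gene of the C1q and tumor necrosis factor family, rose by 2.93. The lectin gene Siglec5 rose by 2.22, Parpbp by 2.02 and the matrix proteoglycan versican, Vcan, by 1.65, while Lrrn2 fell by 1.29.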

How the results depend on the processing

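All results with array quality weights or without the 2 day 1 arrays that stood apart come from alternatives chosen after seeing the data, and the other alternatives were fixed before the data were examined. For the genes named, 299 results under each alternative gave 4234 values, of which 3494 kept their direction and their side of the threshold, 694 lost the call, 46 gained one and 0 reversed. In 30 the sign differed with neither value called. Named calls held under every alternative run for 31 of 49 genes with perchlorate at day 14, for 47 of 58 with both at day 14, and for 10 of 23 with both at day 1. For the diet they held for 1 of 8 at day 1 (Itih3), 4 of 17 at day 14 and 11 of 31 over both days, and for perchlorate on the diet at day 14 for 2 of 17 (Itih3 and Defb1). Among the calls lost under some alternative with perchlorate at day 14 were Mki67, Ccna2, Vwf, Casr and Kl. No paired analysis was possible because the sample numbers are unique to each group. Detection calls were not used here, so the signal over background that limits each probe set is unknown.

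Without the filter more probe sets are tested, and the counts by limma became 6 (diet, day 1), 21 (diet, day 14), 121 (diet, both days), 19 (perchlorate on the diet, day 14), 0 (diet against perchlorate, day 14), 0 and 1 (interaction, day 1 and day 14) and 63 (perchlorate, day 14 minus day 1). The likeness at day 14 became 0.729. A fit of only the groups compared has fewer arrays and its own spread. It called 2, 518 and 546 for the diet (day 1, day 14, both days), 1 and 1244 for perchlorate (day 1, day 14), 19 and 3199 for both together, and 0 and 338 for perchlorate on the diet. It called 0 for diet against perchlorate at day 14, 0 and 6 for the interactions, 32 for perchlorate at day 14 minus day 1 and 1 for the diet at day 14 minus day 1.

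Array quality weights gave 96, 915 and 1339 for the diet, 12 and 1762 for perchlorate, 678 and 4371 for both, and 70 and 961 for perchlorate on the diet. They gave 78 and 17 for diet against perchlorate, 5 and 13 for the interactions and 511 for perchlorate at day 14 minus day 1. The fit without the 2 arrays that stood apart has fewer arrays, but its shared spread no longer holds those 2. Perchlorate on the diet at day 1 uses neither array, and its count went from 1 to 62. The counts were 25, 221 and 406 for the diet and 1426 for perchlorate at day 14. For both they were 341 and 3295, and for perchlorate on the diet 62 and 173. They were 0 and 2 for diet against perchlorate, 0 for the interaction at day 1 and 66 for perchlorate at day 14 minus day 1, and the likeness at day 1 became 0.434. Of the calls with all arrays, these counts share 665 of 665 for perchlorate at day 14, 41 of 41 for the diet at day 14 and 45 of 103 for the difference between days. On the values as deposited the counts were 190 (both, day 1), 23 (perchlorate on the diet, day 14), 1 (diet against perchlorate, day 1) and 0 (interaction, day 1). With a pseudocount of 64 they were 0 (diet against perchlorate, day 14) and 1 (interaction, day 14), and with a pseudocount of 1 the former was 0. For the weights, the values as deposited and the pseudocounts the cause was not tested.

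Leaving out 1 array at a time, the counts ran from 1 to 6 (diet, day 1), 6 to 21 (diet, day 14), 54 to 148 (diet, both days), 0 to 55 (perchlorate, day 1), 225 to 551 (perchlorate, day 14), 60 to 142 (both, day 1) and 808 to 1356 (both, day 14). They ran from 0 to 3 and 2 to 32 for perchlorate on the diet, 0 to 408 and 0 to 2 for diet against perchlorate, 0 to 5 and 1 to 3 for the interactions, and 30 to 317 for perchlorate at day 14 minus day 1. The diet effect at day 14 minus day 1 gave 0 in each, with 399 to 766 probe sets at an unadjusted p under 0.05. The likeness ran from 0.149 to 0.502 at day 1 and from 0.743 to 0.820 at day 14. A group left with 2 arrays shares the spread of the others in the fit.

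Over the 15 comparisons camera gave 360 results for the lists, 148 of them called. With an estimated correlation 146 calls were lost and 0 gained, with the mean of all probe sets of a gene 7 were lost and 8 gained, and on the values as deposited 7 were lost and 19 gained, with 0 reversed. Without the 2 arrays that stood apart, 22 of 345 results lost the call, 10 gained one and 1 reversed. The reversed one was that of C cell markers with perchlorate at day 1, not called with all arrays. With the mean of all probe sets the lost calls were lysosome for the diet (adjusted p = 0.0897) and perchlorate (0.056) at day 14, antioxidant defence for perchlorate on the diet at day 1 (0.0873) and perchlorate at day 14 minus day 1 (0.0731), endoplasmic reticulum folding for perchlorate on the diet (0.0539), adipocytes for diet against perchlorate (0.0561) and mitochondrial phosphorylation for the interaction (0.0532), the last 3 at day 14. As deposited they were lysosome for the diet (0.0595) and perchlorate (0.0897) at day 14, cell cycle (0.338) and immediate early genes (0.0966) for both at day 1, and endoplasmic reticulum folding for diet against perchlorate at day 1 (0.0891). Mitochondrial phosphorylation was lost there for the interaction at day 14 (0.0537) and the diet at day 14 minus day 1 (0.0716). Among the gains as deposited with perchlorate at day 14 were mitochondrial phosphorylation (0.0487) and adipocytes (0.0203). At the main settings they had an adjusted p = 0.775 and 0.761 with an estimated correlation. The cause of these changes was not tested.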

Other observations

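The counts of splits, the clock gene tests, the tests on replicate 18, the array quality weights and the fit without the 2 arrays that stood apart were put in writing after their results were seen.

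Of 14 measured circadian clock genes none passed the test between the untreated controls of the 2 days. Nr1d1, which encodes a repressor of the clock, was at 8.96 ± 0.19 in day 1 controls and 7.52 ± 0.29 in day 14 controls (SD, n = 3), a difference of -1.44 (SE 0.26, adjusted p = 0.24 by limma). Dbp, a transcription factor gene driven by the clock, differed by -1.09 (adjusted p = 0.291), Tef by -0.62 and Per3 by -0.78. The repressor genes Nfil3 and Cry1 differed by 0.93 and 0.81, Per1 by 0.23 and Hlf by 0.07. Of the activators Bmal1 differed by 0.80, Npas2 by 0.29 and Clock by 0.10. By p, Nr1d1 and Dbp ranked 1 and 2 of 18625 probe sets, though limma called 0 between the control days, with 765 at an unadjusted p under 0.05. These genes were chosen after their values were seen.

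Within day 1, Nr1d1 was at 8.79 with perchlorate, 8.10 on the deficient diet and 7.42 with both. At day 14 it was at 7.61, 7.01 and 6.72.

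Nr1d1 and Dbp fell with the deficient diet plus perchlorate at day 1, calls that ended in a fit of only these groups (adjusted p = 0.0545 and 0.0756). The time of day at which the animals were killed cannot be told apart from the treatment. Between control days the 11 output and repressor genes had a median of -0.55, with 7 lower, and the 3 activators one of 0.29. These medians do not decide it, because the activators are few and the same 3 day 1 controls enter the fall. The first median also pools genes that moved both ways (Nr1d1 -1.44, Nfil3 0.93, Cry1 0.81), so it may hide a shift. Day 14 minus day 1 within the treatments shares none of those arrays. There the medians were -0.30 and 0.07 with perchlorate, -0.04 and 0.00 on the diet and -0.26 and -0.15 with both. In the same order of treatments, Nr1d1 differed by -1.18, -1.09 and -0.70, and Dbp by -0.68, -0.11 and -0.29. Quantile normalization and the 2 arrays that stood apart are argued against, since the higher adjusted p of both genes over the values as deposited and the fit without the 2 arrays was 0.0464. An effect of the treatment itself stays open.

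Perchlorate replicate 18 of day 1 stood apart from the other 23 arrays, with a quality weight of 0.0651 against 0.266 in control replicate 22, the next lowest. Loss of RNA from the 5' end is argued against by its GAPDH ratio of 2.52 (log2, 3' to 5' probe set), within 1.60 to 3.43 in the others. Other tissue as the whole cause is argued against by a median of 0.22 in the 2 thyroid lists, with 1042 genes lower by over 1 on the log2 scale. Its lymphocyte and muscle markers stood 3.31 and 2.42 above the other arrays, so some other tissue may add to it. Under-representation of genes with a long genomic span goes with it, at a correlation across genes of -0.453, and no biological explanation was tested.

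The counts of called probe sets were also set against other splits of the same arrays. For the diet over the mean of both days 1 of 100 splits, the real one with 191, gave as many, a share under 0.05. The highest other gave 7, but splits that mix diet and control arrays widen the spread within groups, which lowers their counts. No regrouping of residuals was run for this comparison, so chance is made unlikely for the count but not excluded. For perchlorate at day 1 all 10 splits gave at least the real count of 0 by limma, which no split can fall below, and 5 gave more. The highest, with 1106, put perchlorate replicates 16 and 18 with control replicate 22, which points to a structure of the samples that the groups do not follow. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, so only the real count and the highest other are given for the rest. They were 10 and 0 for the diet at day 1, 41 and 0 for the diet at day 14, 665 and 0 for perchlorate at day 14, 112 and 1 for both at day 1, and 1649 and 0 for both at day 14. For perchlorate on the diet they were 1 and 0 at day 1 and 39 and 0 at day 14, and for diet against perchlorate 2 and 3 at day 1 and 1 and 0 at day 14. For the diet effect at day 14 minus day 1 the real count is 0 by limma, so all 100 splits gave at least as many and the test says nothing about chance. The highest other gave 1.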
